A study of Mus musculus with 21 samples.

How the data were processed

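The series holds 21 CUT&RUN samples of mouse embryonic stem cells. Of these, 16 are H3K4me1 libraries, 2 for each of 8 groups formed by 4 genotypes and 2 states. There are also 1 IgG library of naive wild-type cells and 4 MLL4 libraries of formative wild-type and DKO cells. Per the labels, cells were bound to concanavalin A beads and digested with protein A-MNase, and yeast DNA was added with the stop buffer. Formative cells were collected 63 h after LIF and 2i withdrawal. Wild type and dCD carry the line label R1, while the floxed line and DKO carry none. The labels name different catalogue numbers for the H3K4me1 antibody in different fields. The number in the protocol field is known as that of an H3K27ac antibody, and which was used could not be resolved here. The mark is named as labelled.

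The submitters' processing notes name Trim Galore, Bowtie2, SEACR, DiffBind and deepTools and the build mm10. Versions and the step each tool served are not given in the sources used here, nor is whether the yeast DNA entered the scaling. The only processed table lists 186826 regions with 1 H3K4me1 level per group. Per the submitters' processing notes and the file headers, these deposited levels are log2 values, with the 2 libraries of a group in 1 column. The columns headed CKO were taken as the floxed line, since the descriptions of its samples name merged tracks with that abbreviation. The table also carries the authors' comparison of formative with naive wild-type cells, with a deposited log2 fold, p-value and FDR per region. The authors' deposited log2 fold columns for H3K27ac and for RNA of the nearest gene come from samples outside this series. A fold of 1 in them is a ratio of 2. Another 14 columns of levels, which hold other measures and also have 1 value per group, were not used, nor was a further fold column under the abbreviation AT. IgG background and MLL4 occupancy were not analysed here.

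The levels were found to follow the log2 of 1 plus a constant times normalized reads over the square of the region width. In wild type the offset was 22.2 in both states and the slope on log2 width close to −2. Levels of regions of different width are therefore not comparable, and the added 1 shrinks differences in wide regions, so levels were compared only within a region. They were converted back to normalized reads to describe depth. Median reads per region were 39.2, 37.0, 31.6 and 31.5 in naive wild-type, floxed, DKO and dCD cells, and 37.7, 35.0, 30.6 and 29.6 in the formative groups. In a simulation with every group at wild-type depth, counting noise alone put 0.109% of unchanged regions past a 2-fold difference, all of them under 32 reads. Of 200 regions simulated at 4-fold, 198 passed it. These figures leave out the lower depth of the mutants, and also variation between cultures, which pooled columns do not show.

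Regions had a median width of 1947 bp, from 163 to 57184 bp. Coordinates were taken as starting at 1, since the mitochondrial region runs from 1 to 16299, and the width column gives 1 bp more. All ends lay within the chromosome lengths of the GRCm38 sequence, from which CpG density and GC content were computed. For 271 regions the gene name had been turned into a date, and these were treated as unnamed. Levels were missing for 2 regions. No region had 0 in every group, so no filter on low values was needed. Regions within 1 kb of a start site by the table's own distance were called promoter regions.

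Differences were formative minus naive for the transition, DKO minus the floxed line, dCD minus wild type, and the floxed line minus wild type within a state. Differences of transitions and differences between the DKO and dCD effects were taken as well, for 14 comparisons in all. The design planned a test per region, but pooled columns allow none. Sizes are given instead, without p-values, and only the wild-type transition has a test, the FDR of the authors' deposited table at a threshold of 0.05. A region was counted at a difference of at least 2-fold. A locus was the mean log2 difference over regions within 50 kb whose nearest gene it is, counted at 1.5-fold, and 21535 genes had one.

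Region classes in wild type were the regions gained or lost at that FDR, with stable regions at an FDR above 0.2 and a log2 fold under 0.5 in size. Classes in the floxed line used 2-fold differences, with stable regions under 0.5. Classes from 1 control were read in the other control and its mutant, so that the libraries that defined a class did not enter its value. Intervals of 95% for class medians held the true value in 94.4% of 1000 simulations of 301 independent values. Regions are not independent, and these intervals do not measure variation between libraries. For each of 12 gene lists the median was placed among 10000 random lists matched on read level and number of regions. They were not matched on CpG density or on the share of promoter regions. On data simulated with counting noise, a list of 20 genes shifted by 0.5 reached percentile 100. Of 200 unshifted lists drawn at random, 4.5% lay outside the central 95%. The simulated loci lacked the spread of real differences, so this checks the procedure and not its power or error rate on the real lists. Lum, Pou3f3, Rpl13a and Zic2 had no region within 50 kb.

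The gene lists, the comparisons, the use of region classes, the 1 kb and 50 kb limits and the rule for naming genes were fixed before the data were examined. That rule names the Kmt2c and Kmt2d loci, the 5 regions with the largest increase and the 5 with the largest decrease per comparison, and up to 4 members of each list. The regions had to have mean reads above the median and a start site within 50 kb, predicted genes were passed over, and each gene was used once. Its conditions on significance and replicates could not be applied. Where a list had 5 or fewer members past the size rule, most are named, so a member beyond 4 was named after its values were seen. The size rules, the scale of mean reads, the matching of random lists and the size-based classes were chosen once the table had been read.

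Alternatives planned in advance were centring each group on its median, quantile scaling, 0.5 in place of the added 1, 20 kb in place of 50 kb, 2 kb in place of 1 kb for promoters, and stricter classes. Regions with at least 32 wild-type reads, the data without chromosomes 8, 14, 17 and X, and 2-fold at the locus were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Nearest gene is a convention and does not tie a region to a target.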

Results

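H3K4me1, the histone mark found at enhancers and beside promoters, was profiled in mouse embryonic stem cells by CUT&RUN, in which an antibody directs a protein A-MNase fusion to release the chromatin around its target for sequencing. Cells of 4 genotypes were taken in 2 states: the naive state, held by LIF and 2i, and the formative state, 63 h after LIF and 2i were withdrawn. MLL3 and MLL4, encoded by Kmt2c and Kmt2d, are the main enhancer H3K4 monomethyltransferases. The genotypes were wild type, an MLL3-null line with floxed MLL4 (here the floxed line), a line without either enzyme (DKO), and a line with CD alleles of both (dCD), which stand for catalytically dead enzymes. Each of the 8 groups had 2 H3K4me1 libraries, cultured and prepared independently, but the values analysed here are 1 pooled column per group. No spread between replicates could therefore be computed, differences between lines carry no test, and they are described by size. The table holds levels for 186824 regions, with a median width of 1947 bp and a median of 38.9 normalized reads in wild type. Median reads per region were lower in the mutants, 31.6 in naive DKO and 31.5 in naive dCD against 39.2 in naive wild type and 37.0 in the floxed line. Differences are given as log2 values, coordinates are those of mm10, and a region is named by its nearest gene, which need not be its target.

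The first comparison asked how H3K4me1 differs between naive and formative wild-type cells. The mark moved in both directions: in the authors' deposited table, 18339 regions gained and 19643 lost H3K4me1 at an FDR under 0.05, while 85437 were stable. The largest gain lay in an intron of Nrxn3, a presynaptic adhesion gene (12:88818544–88822094), where the level was higher by 3.48 in formative cells and normalized reads went from 13.4 to 175.4. Its FDR in the authors' deposited table, 4.73e-23, was the smallest of the table. Other large gains lay near Pcsk2, a prohormone convertase gene (2:143539587–143542347, intronic, 3.13), Slc5a7, the choline transporter (17:54301208–54304304, intergenic, 3.00), Gucy1b1, a guanylate cyclase subunit (3:82063286–82066194, intron, 2.85) and Ugt8a (3:125929504–125931806, intron, 2.79). Losses were led by introns of Sptlc1, a serine palmitoyltransferase subunit (13:53363910–53365798, −3.24), and Iars, an isoleucyl-tRNA synthetase (13:49687363–49690225, −2.96). They were followed by regions near Zfp977 (7:42559066–42562588, intergenic, −2.84), Serpina3h (12:104249173–104252232, exon, −2.83) and Trpc4ap (2:155662512–155664610, intron, −2.75). By size alone, 20770 regions were at least 2-fold higher and 21235 at least 2-fold lower. Of these, 65.4% passed the FDR in the authors' deposited table, with 93.1% among regions of at least 32 normalized reads and 45.1% among the rest.

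Averaged over the regions within 50 kb of each gene, the pluripotency lists moved apart in wild type. Of 22 naive pluripotency loci, 10 were at least 1.5-fold lower in formative cells and none higher, with Tfcp2l1 (−1.33), Mras (−1.12) and Jam2 (−1.01) at the front, and next Zfp42, also called Rex1, on chromosome 8, whose median in this comparison was −0.19. Of 23 formative and primed loci, 10 were higher and none lower, led by Fgf5, the standard marker of the formative state (1.59), Sox11 (1.25), Sall2 (1.12) and Sox3 (0.91, on X, whose median was 0.33). The list medians were −0.51 and 0.46, or −0.49 and 0.49 with each group centred on its own median, at percentiles 0.01 and 100 of random lists matched on read level and number of regions. Some loci of later lineages were also higher. The neural list had a median of 0.43 at percentile 99.99, with Pax3 (1.21), Pax6 (0.95), Zic1 (0.79) and Six3 (0.60) among the higher loci and none lower. In the primitive streak and mesoderm list (median 0.40, percentile 99.98) 5 of 15 were higher, Evx1 (1.13), Foxf1 (0.66), Fgf8 (0.65), Eomes (0.65) and Mixl1 (0.62), and the VEGF receptor gene Kdr was lower (−0.65). In the endoderm list, whose median of 0.21 lay inside the central 95% of random lists, 5 of 13 were higher, Afp (1.03), Cer1 (0.81), Dab2 (0.80), Foxa2 (0.61) and Sox17 (0.60), and the laminin gene Lama1 was lower (−0.95). Among 12 fibroblast loci, which would mark feeder cells, 5 were higher: Fap (2.14, a single region), Col1a2 (1.25), Prrx1 (1.13), Dcn (1.13) and Twist1 (0.89). A list of MLL3/4 complex members and other genes of H3K4 methylation, which includes the demethylase genes Kdm1a and Kdm5b, went the other way, with 7 of 16 lower and none higher, among them Paxip1 (−1.22), Kmt2b (−1.02) and Rbbp5 (−0.89). The list of 20 WNT, FGF and TGF-beta genes had a median of 0.25 at percentile 99.98, with Spry4 (0.73) and Id3 (0.59) past the size rule. Esx1 (0.80, on X) was higher and Tfap2c (−0.72) lower among 12 trophoblast genes. Among housekeeping genes Tbp was lower (−0.62), and no locus passed among 12 core pluripotency genes, whose median of 0.14 lay at percentile 97.55, or among 9 germ line genes. Over the 12 lists and 14 comparisons, 56 of 168 list medians lay outside the central 95% of random lists.

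The floxed line, which lacks MLL3 but keeps MLL4, was compared with wild type as the control of the DKO. Its transition resembled that of wild type: 17425 regions were at least 2-fold higher and 19752 lower, and the transitions in the lines correlated at r = 0.78 across regions, which are not independent replicates. Gains near Gucy1b1 (3.14), Nrxn3 (2.89) and Pcsk2 (2.82) recurred, Metrnl (11:121689317–121691895, intergenic, 3.00) and Stag3 (5:138312080–138314906, intergenic, 2.78) joined them, and the largest losses lay near Zfp33b (5:104574615–104577423, intron, −2.89), Zfp977 (−2.78) and Rars (11:35843343–35845815, intronic, −2.73). Of the naive pluripotency loci 9 were lower and none higher, led by Tfcp2l1 (−1.29) and Jam2 (−1.26), and 9 formative and primed loci were higher and none lower, led by Fgf5 (1.58) and Sox3 (1.02). Higher in the floxed line were also 8 neural loci (Pax3 1.22, Pax6 1.06), 6 streak and mesoderm loci (Lhx1 0.78, Fgf8 0.75), endodermal Dab2 (1.03), Afp (1.03) and Cer1 (0.66), and fibroblast Fap (1.73), Dcn (1.32), Col1a2 (1.12), Prrx1 (0.72) and Twist1 (0.62). H3K4 methylation loci were again lower, 6 of 16, led by Paxip1 (−1.06). The Kmt2c locus differed from wild type by −0.06 in naive and −0.12 in formative floxed cells, although 1 intronic region 115 kb from its start site (5:25382739–25384145), named after its values were seen, differed by −0.86 and −2.03. The regions do not check the deletion itself. Within a state, the floxed line and wild type differed less than across states: 1614 regions were at least 2-fold higher and 8183 lower in naive cells, and 982 and 7148 in formative cells. With each group centred, the lower share of these fell from 83.5% to 65.1% and from 87.9% to 70.7%. The region near Elobl (11:88968167–88969508, intergenic) was higher by 3.35 and 3.65, with 329.1 against 31.9 reads in naive cells, whereas regions near H2-T24 (17:36014239–36018385, intron, −3.08) and St6galnac1 (11:116764377–116769165, intron, −2.96) were lower in naive cells. Few list loci reached 1.5-fold: Kdr (−0.71), Meis2 (−0.70) and Hprt (0.62, on X) in naive cells, and Klf2 (−0.61, on chromosome 8, whose median was −0.35) and Setd1a (0.60) in formative cells. The wild-type and dCD lines carry the label R1 and the other lines no line label, so MLL3 loss cannot be separated from line of origin here.

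Loss of MLL4 on top of MLL3 was read from DKO against floxed cells. The Kmt2c locus differed by −0.53 in naive and −0.21 in formative cells and the Kmt2d locus by 0.33 and 0.72, values that say nothing of the deletions, since the regions used need not cover them. In naive cells 29722 regions were at least 2-fold lower in DKO and 8143 higher, and in formative cells 31273 and 12096. The largest deficit in naive DKO lay near Vmn2r106, a vomeronasal receptor gene (17:20306007–20307912, intergenic, −3.75, from 82.3 to 5.5 reads), on a chromosome whose median was −0.50. A region near Scgb2b23-ps (7:33688841–33691389, intergenic) differed by −3.44 in naive and −3.13 in formative cells. In formative DKO the Nrxn3 intron that led the wild-type gains was the lowest of the named regions (−3.16, from 145.9 reads in the floxed line). Others were Lix1 (17:17435813–17439576, intron, −3.07, with a chromosome median of −0.36), Cst3 (2:148884501–148886997, intergenic, −2.94) and Smgc (15:91846735–91849625, intron, −2.92). Higher in DKO were exonic regions of Pnma5 (X:73035006–73037800, 2.59) and Zfp629 (7:127610829–127614636, 2.56) and an intron of Nrros (16:32145965–32148342, 2.33) in naive cells. In formative cells exons at Lipt1 (1:37874584–37876432, 2.83), Ccdc34 (2:110011073–110012870, 2.71) and Pcdha7 (18:36974864–36976625, 2.65) led. The lower share depended on scaling: 78.5% in naive cells became 56.7% with each group centred on its median (15060 higher, 19722 lower) and 56.0% after quantile scaling, and 72.1% in formative cells became 51.3% (20834 higher, 21986 lower) and 54.8%. Centring shifted all differences by 0.21 in both states, and values relative to it are given below as centred.

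Among gene lists, naive pluripotency loci were lower in naive DKO cells. Of the 22, 11 were at least 1.5-fold lower, led by Klf2 (−0.99), Klf5 (−0.97) and Prdm14 (−0.84), and Nr0b1, on X, was higher (1.19). After centring only 3 of the 11 passed, Klf2, Klf5 and Prdm14. The list median was −0.56, centred −0.35, at percentile 0.07 of random lists, and 8 of the 11 lay outside the chromosomes with shifts of their own (8, 14, 17 and X). Klf5 lies on chromosome 14, whose median was −0.48, and stood −0.50 from it. Klf2 lies on chromosome 8, whose median was 0.00. In formative DKO cells the formative and primed list stood lower: 12 of 23 loci were lower and none higher, 7 of them after centring, with a median of −0.59, centred −0.38, below every random list. Sox3, a SOXB1 factor, lay −1.42 from the median of X, itself −0.58, and was the lowest locus of the list. Sall2 on chromosome 14 (chromosome median −0.39) differed by −1.04, Car14 by −1.01 and Fgf15 by −0.96. In naive DKO cells 5 members of this list were lower, Sox3 (−1.04 from the median of X), Pim2 (−0.82, on X), Sall2 (−0.82), Otx2 (−0.68, on chromosome 14) and Fgf15 (−0.66), while Fgf5 was higher (0.78). The median of this list there was −0.41, centred −0.20, at percentile 0.72. It thus stood lower in both states on deposited and centred levels. After quantile scaling the median was −0.04 in naive and −0.39 in formative cells, so the naive deficit depended on scaling. In formative DKO cells 5 naive pluripotency loci were lower, Fgf4 (−1.02), Socs3 (−0.93), Tbx3 (−0.83), Klf5 (−0.77) and Tdh (−0.68, on chromosome 14), and Klf4 was higher (0.66). The naive list median there, −0.23, centred −0.02, lay inside the central 95% of random lists, at percentile 4.55. Core loci that passed included Pou5f1 (−0.86), Zfp281 (−0.73) and Sall1 (−0.60) in naive cells, and Sall4 (−0.74), Sox2 (−0.70) and Pou5f1 (−0.70) in formative cells. The core medians were −0.48 and −0.36, centred −0.26 and −0.15, at percentiles 3.26 and 2.09. Of these core loci only Pou5f1 in naive cells passed after centring. Pou5f1 (Oct4) is on chromosome 17, and stood −0.36 and −0.34 from its chromosome's median. Targets of WNT, FGF and TGF-beta signalling were lower at 6 of 20 loci in naive cells, led by the FGF antagonists Spry4 (−0.98) and Spry2 (−0.93, on chromosome 14), and at 9 in formative cells, led by the Nodal antagonist gene Lefty1 (−1.04) and Sp5 (−1.03). The naive list median of −0.41 lay inside the central 95% of random lists, at percentile 6.99, and the formative median was −0.50, centred −0.30, below every random list.

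Across the lineage lists, loci passed in both directions in DKO. Neural loci were the highest list in naive cells, with a median of 0.25, centred 0.46, at percentile 99.99, with Zic1 (0.82) among those passing. Random lists were not matched on CpG density, with which the differences of distal regions rose (below). Percentiles in DKO and dCD may reflect it, which was not tested. In formative cells Pax6 (−1.06) and Pax3 (−0.60) were lower. Streak and mesoderm loci gave Lhx1 (0.79) and Msgn1 (−1.11) in naive cells and T (−0.76, on chromosome 17) and Eomes (−0.60) in formative cells. Endoderm loci gave Dab2 (0.73) and Gata6 (−0.80), and then Foxa2 (−0.94). Of the 12 trophoblast loci Ascl2 (−1.20), Tfap2c (−1.04), Id2 (−0.75) and Bmp4 (−0.68, on chromosome 14) were lower in naive cells, and Ascl2 (−0.74), Gata3 (−0.74), Id2 (−0.68), Krt18 (−0.64) and Bmp4 (−0.62) in formative cells. Fibroblast Fap was higher (1.01) and Col3a1 lower (−0.81) in naive cells, and Col3a1 (−0.97), Fap (−0.95), Col1a2 (−0.81) and Dcn (−0.80) were lower in formative cells. In the germ line list Nanos3 (−0.86, on chromosome 8), Prdm1 (−0.79) and Stk31 (−0.71) were lower in naive cells, and in formative cells Ddx4 was higher (1.01) and Dazl (−0.59, on chromosome 17) and Prdm1 (−0.59) lower. Housekeeping Tbp (−0.63, on chromosome 17) and Hprt (−0.59, on X) were lower in naive cells, each near its chromosome's median (−0.13 from it in both), and Sdha was higher (0.87) and Hprt lower (−0.70) in formative cells. Their list medians, −0.18 and −0.08, turned to 0.03 and 0.13 when centred. H3K4 methylation loci stood apart in formative DKO, with Kmt2b (1.21), Ash2l (0.89, on chromosome 8), Setd1a (0.83), Paxip1 (0.77) and Kmt2d (0.72) higher, none lower and a median of 0.33, centred 0.54, at percentile 99.90. In naive DKO Kdm5b (−0.77) and Rbbp5 (−0.70) were lower in that list, whose median of −0.17 turned to 0.04 when centred.

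The dCD line, which should keep both proteins without their activity, was compared with wild type. Kmt2c differed by −0.17 and −0.29 and Kmt2d by 0.24 and 0.52 in naive and formative cells. In naive dCD 26023 regions were at least 2-fold lower and 2891 higher, and in formative dCD 37516 and 4839. Lower regions included introns of Chd9 (8:90858899–90860484, −2.50), Glipr2 (4:43967595–43969121, −2.43) and Lama3 (18:12507693–12510696, −2.34) in naive cells. In formative cells they lay near the olfactory receptor gene Olfr24 (9:18720938–18723411, intergenic, −3.23), Syt7, a synaptotagmin gene (19:10377020–10379060, intergenic, −3.10), and the same Scgb2b23-ps region as in DKO (−3.09). Chd9 lies on chromosome 8, whose medians in dCD were −0.57 and −0.45. Higher regions were fewer and smaller, with an exon of Pcdha11 (18:37010426–37011697, 1.75) and the Mob2 promoter (7:142060823–142062488, 1.73) in naive cells, and introns of Iars (2.36), Zfp955a (17:33252691–33254194, 2.20) and Uqcrc1 (9:108938243–108941136, 1.96) in formative cells. Centring, which shifted all differences by 0.35 and 0.40, turned the direction of the majority: the lower share went from 90.0% to 45.3% in naive cells (12713 higher, 10523 lower) and from 88.6% to 47.3% in formative cells (20140 higher, 18102 lower), while quantile scaling gave 55.9% and 56.5%.

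Naive pluripotency loci were lower in naive dCD at 12 of 22 and higher at none, led by Klf2 (−1.15, on chromosome 8), Zfp42 (−0.84, on chromosome 8), Fgf4 (−0.81) and Prdm14 (−0.80). The list median was −0.61, centred −0.26, below every random list. Only Klf2 stayed past the rule after centring, and it stood −0.58 from its chromosome's median, just short of the rule. In formative dCD 8 were lower, led by Fgf4 (−1.36), Dppa5a (−0.88) and Dppa3 (−0.80), and the median was −0.46, centred −0.06, at percentile 0.03. Formative and primed loci were lower at 6 of 23 in naive cells, led by Sox3 (−0.93, on X) and Fgfr1 (−0.91, on chromosome 8), with a median of −0.35 that turned to 0.01 when centred. In formative dCD 10 were lower, led by Sox3 (−1.38), Sox11 (−1.07), Pim2 (−0.99, on X) and Pou3f1 (−0.87), with a median of −0.55, centred −0.15, and Sox3, Sox11 and Pim2 passed after centring. The X medians were −0.39 and −0.68. Measured from the X median in formative dCD, Sox3 stood at −0.70 and Pim2 at −0.31. Core loci that passed included Sall1 (−1.11, on chromosome 8) in naive cells and Sall1 (−0.84), Mycn (−0.77) and Sall4 (−0.70) in formative cells. Of these only Sall1 in naive cells passed after centring, and it stood −0.54 from the median of chromosome 8. The core medians were −0.29 and −0.46, centred 0.06 and −0.06. Signalling targets were lower at 6 of 20 loci in naive and 12 in formative cells and higher at none, with Lefty1 (−1.38 and −1.08) and Spry2 (−1.09 and −0.89) among them, and medians of −0.39 and −0.62, centred −0.04 and −0.22. After centring Lefty1 passed in both states, and Spry2 in naive but not in formative cells. Endodermal Afp (−0.86), Cer1 (−0.75), Foxa2 (−0.74), Dab2 (−0.61) and Cxcr4 (−0.59) were lower in formative dCD, none of them past the rule after centring, and Lama1 (−0.89, on chromosome 17) was lower in naive dCD. The endoderm medians, −0.13 in naive and −0.24 in formative dCD, turned to 0.22 and 0.16 when centred, and in naive cells the 4 loci then past the rule, Sox17, Dab2, Afp and Cer1, were all higher. Of the neural loci Sox1 (−0.77, on chromosome 8) was lower in naive cells, and Pax3 (−0.71), Pax6 (−0.68) and Sox1 (−0.59) in formative cells. Their medians were 0.01 and −0.02, centred 0.36 and 0.38. In the streak and mesoderm list Lhx1 was higher (0.72 and 0.82) and Gsc lower (−0.71 and −0.78), with Eomes lower in formative cells (−0.75), and the formative median of −0.30 turned to 0.10 when centred. Trophoblast Ascl2 was lower in both states (−1.09 and −0.94), with Tfap2c (−0.80) and Id2 (−0.67) in naive cells and Gata3 (−0.68) in formative cells. After centring, of these only Ascl2 in naive cells passed, and the only trophoblast locus past the rule in formative cells was higher. The trophoblast medians, −0.23 and −0.15, turned to 0.12 and 0.25 when centred. Fibroblast Col3a1 was lower (−0.99) and Fap higher (0.66) in naive cells, and Col3a1 (−1.22), Fap (−1.07), Dcn (−0.79), Col1a2 (−0.73) and Tgfbi (−0.71) were lower in formative cells. Germ line Nanos3 (−1.11 and −0.70, on chromosome 8) and Prdm1 (−0.70 in both) were lower, and Ddx4 (0.72) was higher in formative cells. After centring, neither Prdm1 nor Nanos3 in formative cells passed, and the majority past the rule was higher in both states. Nanos3 in naive cells stood −0.54 from the median of chromosome 8. The germ line medians, −0.29 and −0.23, turned to 0.06 and 0.17 when centred. H3K4 methylation loci gave Rbbp5 (−0.72) in naive cells and Setd1a (1.03) and Kmt2b (0.77) in formative cells, with a formative median of 0.24, centred 0.64. No housekeeping locus passed in naive dCD, and Sdha (0.63) was higher and Hprt (−0.73, on X) lower in formative dCD.

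To compare the transition itself, gained and lost regions were defined in 1 control line and read in the other control and in the mutant, so that no libraries were shared. Regions that gained H3K4me1 in wild type differed by a median of 1.02 between states in the floxed line and 0.15 in DKO, which is 14.8% of the control. Regions that lost it differed by −1.01 and −0.15 (14.7%). With classes from the floxed line, gained regions differed by 1.34 in wild type and 0.19 in dCD (14.2%), and lost regions by −1.08 and −0.34 (31.2%). In formative cells the gained regions were lower in DKO than in floxed cells by a median of −1.08, with 54.7% at least 2-fold lower, and in dCD than in wild type by −1.16, with 60.2% at least 2-fold lower. In naive cells the same gained regions differed by −0.10 in DKO, which turned to 0.11 when centred, and by 0.01 in dCD. The lost regions, which carry the mark in naive controls, differed in naive cells by −0.62 in DKO and −0.73 in dCD. In formative cells the lost regions differed by 0.25 in DKO and 0.05 in dCD on deposited levels. Both states thus entered their smaller transition in DKO. With each group centred the lost regions in naive cells stood at −0.41 and −0.39, and the gained regions in formative dCD at −0.75. Whether a rise of background reads enters the smaller transitions was not tested. Across all regions 2234 were at least 2-fold higher and 2330 lower in the DKO transition, and 2556 and 4611 in that of dCD. Most of these had few reads: of the 111035 regions with at least 32 reads, 886 passed in either direction in DKO and 2109 in dCD. Of the regions gained in wild type, 9366 were at least 2-fold higher in the floxed line, 698 in DKO, 919 in dCD and 112 in both mutants. The difference of transitions passed 2-fold upward at 19062 and downward at 18726 regions for DKO minus floxed, and at 14923 and 20446 for dCD minus wild type.

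**Figure D1:**
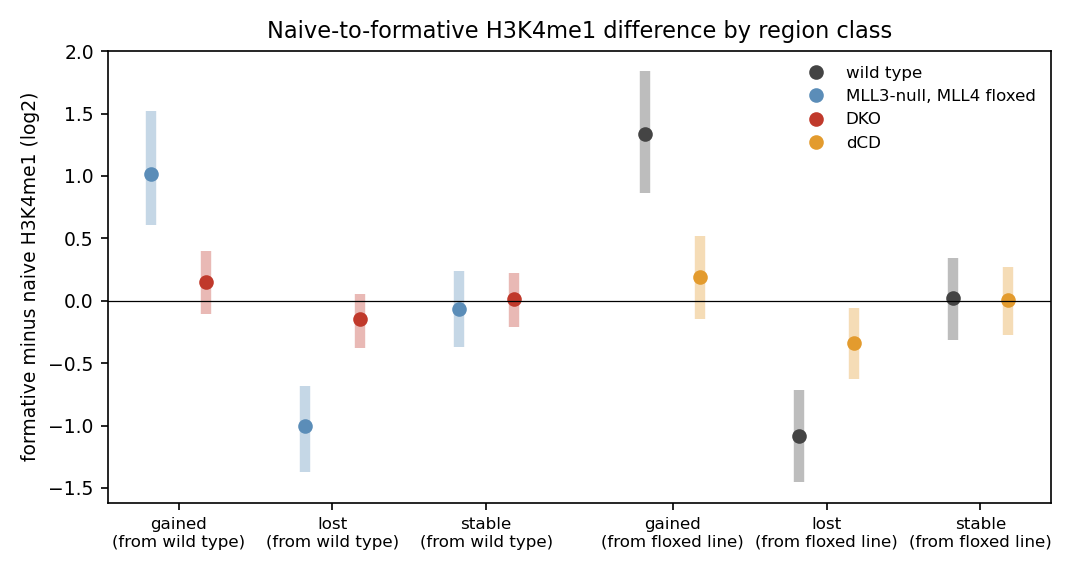
Formative minus naive H3K4me1 (log2) of regions gained, lost or stable in wild type (left, read in the floxed line and DKO) or in the floxed line (right, read in wild type and dCD); points are medians over regions and bars run from the lower to the upper quartile. Gained regions sat at 1.02 in the floxed line and 1.34 in wild type against 0.15 in DKO and 0.19 in dCD.

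Some regions differed between states in the mutants, which need not be a remainder of the control's transition. Of 2234 regions higher and 2330 lower in the DKO transition, 805 and 635 passed 2-fold likewise in the floxed line, and 391 were opposite. Of 2556 and 4611 in dCD, 1355 and 1659 passed likewise in wild type, and 395 were opposite. The regions named next were picked as extremes within each mutant. The largest differences in DKO were higher in formative cells at introns of Olfm3 (3:114903948–114905653, 1.63), Tspan9 (6:128140332–128141470, 1.54) and Ldb2 (5:44752823–44755005, 1.52), and lower at introns of Fbxo15, a gene active in naive cells (18:84937044–84939662, −1.89), Acsl1 (8:46490194–46492204, −1.64) and Tbx3 (5:119677070–119679490, −1.56). In dCD they were near Mettl22 (16:8460564–8461967, intergenic, 1.84) and in Glipr2 (1.82), and in Rnd3 (2:51136096–51138213, exon, −2.48) and Slc38a4 (15:97036227–97039003, intronic, −2.18). At the level of loci, no naive pluripotency gene passed 1.5-fold in DKO, where Fgf4 was the largest (−0.58) and the list median was −0.23. In dCD Zfp42 (−0.66), Klf4 (−0.59) and Fgf4 (−0.59) passed, with a median of −0.28. The formative and primed list kept a median of 0.26 in DKO, with Pim2 passing (0.73), and of 0.24 in dCD, with Fgf5 (1.05) and Sall2 (0.79) passing, all 4 medians lying outside the central 95% of random lists. Neural Zic1 (0.68), streak and mesoderm Lhx1 (0.66) and Foxf1 (0.63), and Lefty1 (0.66) also passed in dCD, among others, and no locus of the remaining lists passed in either mutant. The difference of transitions, DKO minus floxed, was −1.17 at Fgf5, −1.09 at Car14, −1.08 at Pax6, −1.06 at Pax3 and −1.96 at the single Fap region, and positive at Prdm14 (1.07), Zfp42 (0.90), Jam2 (0.86), Paxip1 (1.01) and Rbbp5 (1.01). As a list, naive pluripotency loci did not stand out in this difference, with a median of 0.19 at percentile 49.65 for DKO and of 0.18 at percentile 73.81 for dCD. The formative and primed list did, with −0.20 and −0.22, both at percentile 0.02. For dCD minus wild type it was −0.72 at Sox11, −0.97 at Pax3 and −1.14 at Afp, and positive at Tfcp2l1 (0.78), Paxip1 (1.04) and Kmt2b (0.83). Among regions the most negative differences of transitions were at Metrnl (−2.81) and Pde2a (7:101434202–101437329, intron, −2.70) for DKO, and at Pcsk2 (−3.19) and Ism1 (2:139640239–139642879, intergenic, −3.14) for dCD. The most positive lay at Itch (2:155141089–155144391, intron, 2.96) for DKO and at Sptlc1 (3.73) for dCD.

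**Figure D2:**
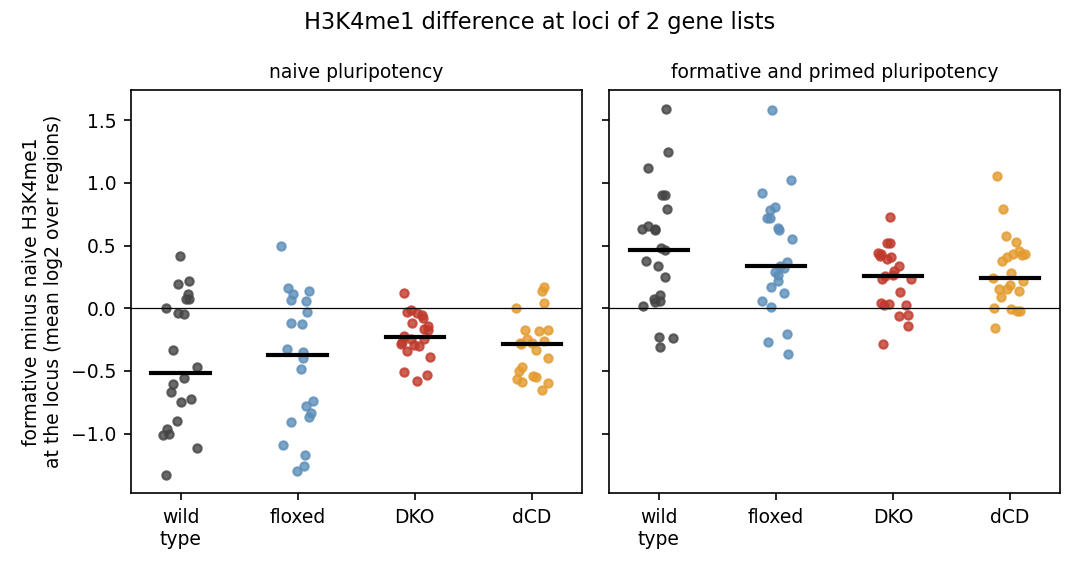
Formative minus naive H3K4me1 at each locus (mean log2 difference over regions within 50 kb) for 22 naive pluripotency and 23 formative and primed pluripotency genes in the 4 lines; each point is a locus and bars are medians. The naive list medians were −0.37 in the floxed line and −0.23 in DKO, and the formative list medians 0.33 and 0.26.

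The DKO and dCD effects were compared, each against its own control. Floxed cells already lack MLL3, so the DKO effect is loss of MLL4 in cells without MLL3. The dCD effect is loss of both activities against wild type. Starting points and line labels thus differ between them, and protein loss and loss of activity are not compared alone. Across regions the DKO and dCD differences correlated at r = 0.63 in naive and 0.73 in formative cells. In naive cells 14681 regions were at least 2-fold lower in both, where independent lists would share 4140.0, and in formative cells 21520, where they would share 6279.9. No libraries were shared between these comparisons. Centring left 5984 and 10621 such regions. It also lowered the number of lower regions in each mutant, so these are not to be set against 4140.0 and 6279.9. On deposited levels, regions that differed at least 2-fold in opposite directions numbered 179 and 127, where independent lists would give 1594.2 and 3239.0. The value in DKO, each mutant against its control, stood at least 2-fold above that in dCD at 13364 regions and below it at 6703 in naive cells, and at 14563 and 4437 in formative cells. Centring, which shifted these by −0.14 and −0.19, turned the naive majority, with 9232 above and 10190 below, and left 8853 above and 8152 below in formative cells. Quantile scaling shifted the medians of these differences less, by −0.09 and −0.15. Among the named regions DKO stood above dCD near Vps53 (11:76159208–76162477, intron, 2.74) and Dph5 (3:115905808–115907776, intron, 2.41) in naive cells. In formative cells it did so in an intergenic region next to Zfp42 (8:43310114–43311515, 3.03) and in an intron of Rims2 (15:39239614–39241835, 3.02). It stood below dCD near Sptlc3 (2:139493004–139496008, intron, −2.37) in naive cells, and at the Selplg promoter (5:113829869–113831232, −1.91) and in Notch3 (17:32142733–32145400, intron, −1.88) in formative cells. Zfp42 lies on chromosome 8, where the medians of this difference were 0.51 and 0.44, and Notch3 on chromosome 17, where they were −0.31 and −0.19. List loci past 1.5-fold in naive cells were Nr0b1 (0.79), Tbx3 (−0.62), Fgf5 (0.75), Fgfr1 (0.72), Sall2 (−0.71), Cldn6 (−0.64), Kdr (0.87), Msgn1 (−0.64), Sox1 (0.77), Tbp (−0.80) and Sp5 (0.60). In formative cells they included Zfp42 (0.99), Klf4 (0.79), Sox3 (−0.62), Sall2 (−0.60) and Ash2l (0.67). Of these Zfp42, Fgfr1, Sox1 and Ash2l lie on chromosome 8, Sall2 on 14, Cldn6 and Tbp on 17, and Nr0b1 and Sox3 on X. The medians of this difference were −0.07 and 0.11 on X and −0.26 and −0.11 on 14.

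H3K4me1 did not differ alike at promoters and distal regions. The 10671 regions within 1 kb of a start site had median differences of 0.38 and 0.40 in naive and formative DKO and 0.41 and 0.47 in dCD, whereas the 176153 distal regions had −0.22, −0.17, −0.32 and −0.33. With each group centred the promoter medians were 0.59, 0.61, 0.77 and 0.87, and the distal medians −0.01, 0.04, 0.03 and 0.07, so that only the difference between the classes is unaffected by centring. Among distal regions the difference followed CpG density. In the decile with the fewest CpGs, a median of 0.39 per 100 bp, the medians were −0.86 and −1.01 in naive and formative DKO and −0.68 and −1.07 in dCD. In the decile with the most, 2.40 per 100 bp, they were 0.32, 0.53, 0.26 and 0.38. The floxed line against wild type did not show this course. In naive cells its medians went the other way, from 0.05 in the lowest to −0.11 in the next to highest decile, with −0.03 in the highest, and in formative cells they lay between −0.16 and −0.07. Within bins of equal CpG density promoters and distal regions differed by 24.7%, 1.02%, 30.4% and 23.7% of the whole difference, in the same order.

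**Figure D3:**
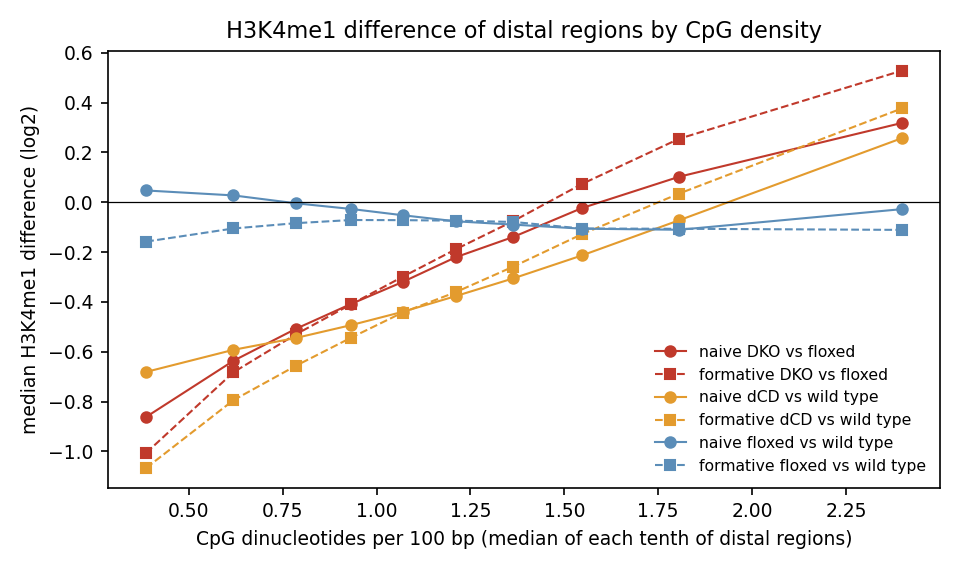
Median H3K4me1 difference (log2) of distal regions against their CpG density (median CpGs per 100 bp of each decile) for DKO against the floxed line, dCD against wild type and the floxed line against wild type; circles are naive and squares formative cells. Formative DKO medians ran from −1.01 to 0.53 and naive floxed medians from 0.05 to −0.03.

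The same table carries the authors' comparisons of H3K27ac, a mark of active enhancers, over these regions and of RNA of the nearest gene in wild type and DKO. RNA followed the number of gained regions in both genotypes, in the authors' deposited table. The median RNA difference of genes with 0, 1, 2 to 3, 4 to 7 and at least 8 gained regions was 0.07, 0.44, 0.95, 1.82 and 3.16 in wild type, and 0.14, 0.41, 0.80, 1.32 and 2.12 in DKO, from the authors' deposited table. Compared directly in formative cells, RNA in DKO minus wild type had medians of 0.08, 0.07, −0.01, −0.14 and 0.01 in these groups in the authors' deposited table. The groups held 8187, 1596, 796, 216 and 35 genes. H3K4me1 of the gained regions in the last 4 groups differed by 0.71, 0.89, 1.01 and 1.13 in the floxed line and by 0.16, 0.14, 0.11 and 0.21 in DKO. H3K27ac of these regions differed by 0.92, 1.11, 1.37 and 2.11 in wild type and 0.31, 0.44, 0.59 and 0.86 in DKO, in the authors' deposited table. Fgf5, with 10 gained regions, had RNA differences of 6.09 in wild type and 5.75 in DKO in the authors' deposited table, while H3K4me1 over those regions differed by 1.78 in the floxed line and 0.41 in DKO. Pou3f1, a POU factor of formative cells, had 5.24 and 5.19 in the authors' deposited table, with H3K4me1 at 0.91 and 0.42 over 9 regions. Smaller RNA differences in DKO were listed for Fgf15 (5.27 in wild type, 2.80 in DKO), Wnt8a (5.32 and 3.19) and Sox11 (3.94 and 2.57) in the authors' deposited table. In formative cells RNA in DKO minus wild type was −1.15 for Fgf15, −1.98 for Wnt8a and 0.03 for Sox11, and in naive cells 1.33, 0.15 and 1.40, in the authors' deposited table. Of 20 formative and primed genes, 15 in wild type and 18 in DKO were at least 2-fold higher, and Nkx1-2 was lower in both, with list medians of 3.37 and 2.82, in the authors' deposited table. Of 21 naive pluripotency genes, 17 in wild type and 16 in DKO were at least 2-fold lower in the authors' deposited table, Tfcp2l1 by −2.86 and −2.76 and Zfp42 by −2.78 and −1.14. The list medians were −2.78 and −1.91 in the authors' deposited table. Nr0b1 parted, at −3.24 in wild type and 0.87 in DKO in the authors' deposited table.

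**Figure D4:**
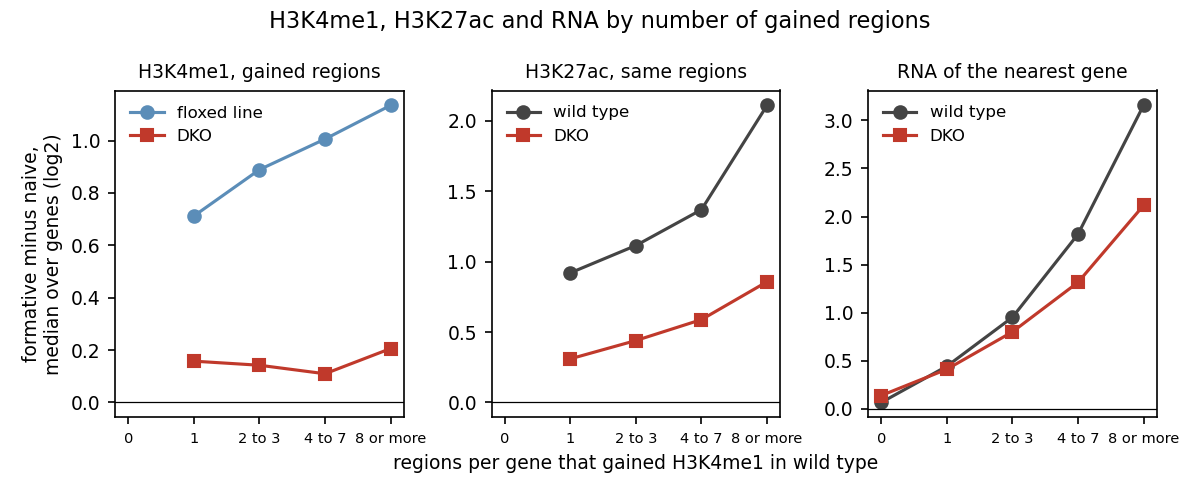
Median formative minus naive difference (log2) of H3K4me1, H3K27ac and RNA for genes grouped by how many of their regions gained H3K4me1 in wild type; H3K27ac and RNA are from the authors' deposited table, and each point is a median over genes. With at least 8 gained regions the DKO medians were 0.21 for H3K4me1, 0.86 for H3K27ac and 2.12 for RNA.

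Several chromosomes had a median of their own. Chromosome 8 differed from wild type by −0.45 and −0.35 in naive and formative floxed cells and by −0.57 and −0.45 in dCD, and DKO differed from the floxed line there by 0.00 and 0.02, where the medians over all regions were −0.18 and −0.13. Measured from the other autosomes, chromosome 8 stood at −0.44 and −0.28 in the floxed line and at −0.30 and −0.18 in dCD. Chromosomes 14 and 17 were lower in DKO than in the floxed line, by −0.48 and −0.39 and by −0.50 and −0.36, and X differed by −0.46 and −0.58 in DKO and −0.39 and −0.68 in dCD. Without these 4 chromosomes, a choice made after seeing the data, 77.1% and 70.5% of the 2-fold regions were lower in DKO and 89.0% and 87.9% in dCD.

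**Figure D5:**
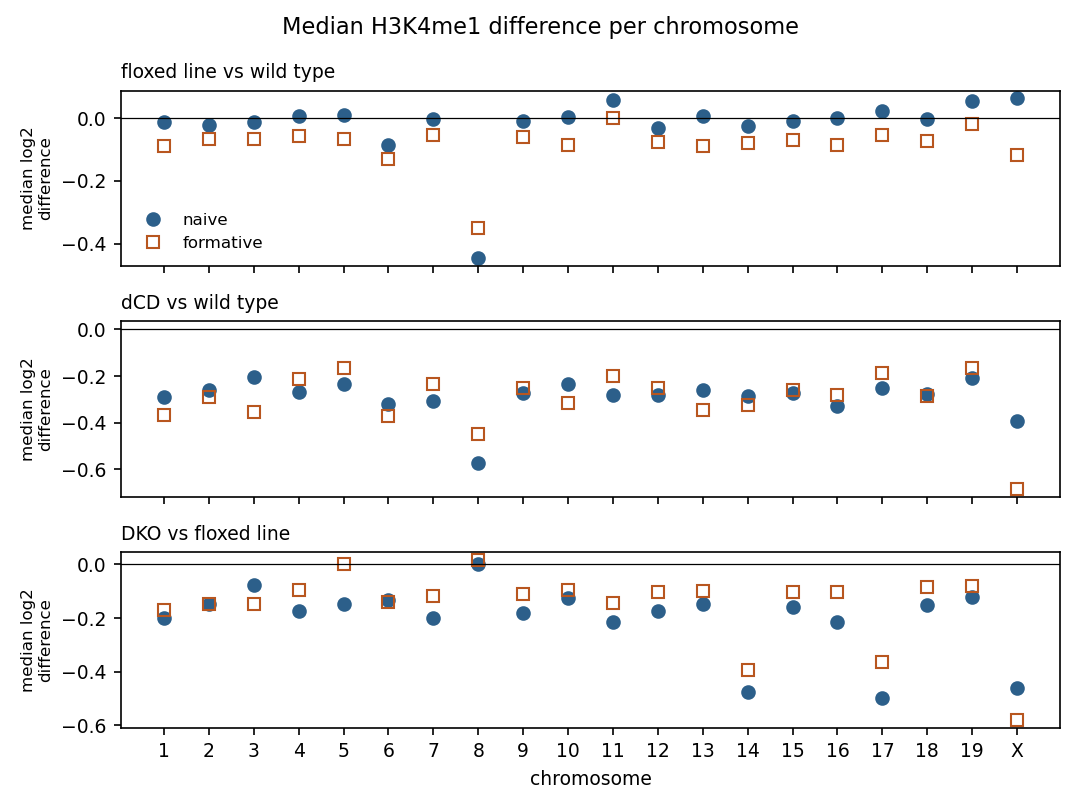
Median H3K4me1 difference (log2) of the regions of each chromosome for the floxed line against wild type, dCD against wild type and DKO against the floxed line; filled circles are naive and open squares formative cells. Chromosome 8 sat at −0.45 and −0.35 in the floxed line, and chromosomes 14 and 17 at −0.48 and −0.50 in naive DKO.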

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

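Of the tests below, those of scaling and of line of origin were chosen only after the result was seen. At 12 regions and 1 locus among the named ones, 2 groups moved at least 2-fold, or 1.5-fold for the locus, in opposite directions under the same contrast. None of these differences was tested, since each value rests on pooled columns, and the regions were picked as extremes by the naming rule. In all, 761 regions differed at least 2-fold in opposite directions in naive and formative DKO against the floxed line, and 1020 in dCD against wild type. Independent lists would give more, 3287.4 and 1254.6. Of the 761 and 1020 regions, 60 and 28 had reads above the median.

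The intron of Itch (2:155141089–155144391) stood at −1.72 in naive and 1.24 in formative DKO, a difference of −2.96. Spdye4c (2:128612209–128615364) stood at −1.36 and 1.56 (difference −2.93), and Rars at −1.08 and 1.52 (difference −2.60). In dCD, Sptlc1 stood at −2.09 in naive and 1.63 in formative cells (difference −3.73), and Trpc4ap at −1.48 and 1.01 (difference −2.49). Pcsk2 went the other way, from 1.17 to −2.02 (difference 3.19). Such a difference between states equals the transition of the control minus that of the mutant. A large transition of the control alone can therefore give opposite signs. Sptlc1, Trpc4ap and Pcsk2 were among the largest transitions named in wild type, and Rars among those in the floxed line. Between mutants in naive cells, Dph5 was higher in DKO and stood at −1.22 in dCD (difference 2.41), and Lrp2bp, on chromosome 8, at 1.10 and −1.21 (difference 2.31). In formative cells the region upstream of Zfp42, on chromosome 8, stood at 1.98 in DKO and −1.06 in dCD (difference 3.03), and Rims2 at 1.66 and −1.35 (difference 3.02). Over the transition, Arhgef28 (13:98185642–98188276) stood at 1.29 in the floxed line and −1.14 in DKO (difference 2.43), and Vmn2r106, on chromosome 17, at −1.04 and 1.30 (difference −2.35). The single Fap region stood at 1.01 in naive and −0.95 in formative DKO (difference 1.96), and at 0.66 and −1.07 in dCD (difference 1.73).

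A first pattern is the lower median of chromosome 8 in the other lines than in wild type and of chromosomes 14 and 17 in DKO. If copy number differed, every stratum of a chromosome should shift alike, and the farthest stratum lay −0.13 from the shift of chromosome 8 and −0.12 from that of 14 or 17. The bound of 0.25 set for this was too wide to decide, since the smallest shifts were 0.18 and 0.25 in size and the strata of chromosome 8 in formative dCD ran from −0.06 to −0.31. In the floxed line against wild type they were closer together, from −0.40 to −0.46 in naive and from −0.26 to −0.31 in formative cells. Scaling of the libraries would move all chromosomes together, yet chromosome 8 departed at least 1.70 times as far from the other autosomes as any of those did. A difference in copy number was neither shown nor excluded, counting copies from genomic DNA of these lines would test it, and no biological explanation was tested.

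Another pattern is the higher level at promoter regions in DKO and dCD. Within bins of equal GC content at least 70.2% of the difference from distal regions was left, and within width bins without the added 1 at least 99.1%. A single factor per library leaves a difference between classes of region as it is, so the smallest difference, 0.57, is no test of scaling. Scaling that depends on the level was not checked for promoters. The floxed line against wild type showed at most 31.4% of the difference. Within bins of equal CpG density, however, only 24.7%, 1.02%, 30.4% and 23.7% was left in naive and formative DKO and dCD. Most of it thus went with CpG density, and whether the rest is particular to start sites was not tested. A rise of background reads after specific signal is lost stays open, since no IgG value was used here.

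The last pattern is the course with CpG density among distal regions. The medians of the highest and lowest decile differed by at least 0.94 and at most 1.53. Within bins of equal GC content at least 71.5% of the difference between CpG-rich and CpG-poor regions was left, and within bins of equal read density at least 67.3%. A hypothesis is that proteins binding unmethylated CpGs could bring other methyltransferases to these regions, and the same background as above remains open. Mapping such a protein and the IgG control over these regions would test both.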

How the results depend on the processing

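Alternatives with at least 32 reads, without chromosomes 8, 14, 17 and X, and at 2-fold for loci were chosen only after the result was seen. No paired analysis was possible because the columns carry no replicate numbers. Leaving out libraries, blocking by replicate, a count-based test, other samples in the fit and a correlation between list members were not run, as they need replicate values. A low-value filter removed nothing, so it moves no value. Of the named regions, chosen as extremes, 80 moved by 0.1 or more with centring and 60 did not. The counts were 89 and 51 with quantile scaling and 13 and 127 with 0.5 added. Centring shifts all regions of a comparison alike, so its count follows from the shifts by construction. Of the 56 list medians outside the central 95%, 52 stayed on the same side with quantile scaling and 46 within 20 kb. Centring moves a list and its random lists alike, so it cannot change a percentile. Depth limits regions under 32 reads, where 0.270% of simulated unchanged regions passed 2-fold by counting noise at wild-type depth. Except where construction shows it, the cause was not tested for any value below.

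With only the 111035 regions of at least 32 reads, fewer regions passed 2-fold by construction. In naive and formative cells 20664 and 22722 passed for DKO, 15384 and 22214 for dCD, and 2743 and 2294 for the floxed line. For the transition 17714 passed in wild type, 17740 in the floxed line, 886 in DKO and 2109 in dCD, and for its difference 16555 in DKO and 13193 in dCD. For the effect difference 6172 and 5773 passed.

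Class medians below lay outside the 95% interval of the value on deposited levels. That interval is over regions, which are not independent, and leaves out variation between libraries. For regions gained in wild type, the floxed transition of 1.02 was 1.05 centred, 1.12 quantile-scaled, 1.03 with 0.5 added and 1.31 with stricter classes. That of DKO was 0.18 centred and 0.17 with stricter classes. For regions lost in wild type, the floxed value was −0.97 centred, −0.90 quantile-scaled, −1.03 with 0.5 added, −1.20 stricter and −1.02 without the 4 chromosomes. That of DKO was −0.12 centred, −0.14 quantile-scaled and −0.18 stricter. For regions gained in the floxed line, the wild-type value was 1.73 stricter, and that of dCD 0.25 centred, 0.23 quantile-scaled and 0.25 stricter. For regions lost there, the wild-type value was −1.11 quantile-scaled and −1.41 stricter, and that of dCD −0.28 centred, −0.28 quantile-scaled and −0.40 stricter. Formative DKO against floxed at gained regions was −0.88 centred, −0.86 quantile-scaled, −1.10 with 0.5 added, −1.27 stricter and −1.05 without the 4 chromosomes. Naive DKO at lost regions was −0.41, −0.34, −0.64 and −0.74 under centring, quantile scaling, 0.5 added and stricter classes. Formative dCD against wild type at gained regions was −0.75 centred, −0.76 quantile-scaled, −1.33 stricter and −1.15 without the 4 chromosomes. Naive dCD at lost regions was −0.39, −0.49, −0.90 and −0.71 under the same settings. The cause was not tested.

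Promoter medians in naive and formative DKO and dCD were 0.34, 0.38, 0.37 and 0.43 within 2 kb, and 0.59, 0.61, 0.77 and 0.87 centred. Regions lower in both mutants numbered 5984 centred, 7322 quantile-scaled and 9247 with at least 32 reads in naive cells, and 10621, 10901 and 12341 in formative cells. The cause was not tested.

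In some lists the majority of the members past 1.5-fold turned direction, and the cause was not tested. At 2-fold only Nr0b1 passed among naive pluripotency loci in naive DKO, 1 higher. Of H3K4 methylation loci 1 passed centred and 5 quantile-scaled in naive DKO, 3 and 3 in naive dCD, all but 1 higher, and 1 lower in the centred formative effect difference. Of streak and mesoderm loci 2 passed centred and 2 quantile-scaled in formative dCD, all higher. Of endoderm loci 3 passed centred in formative DKO (2 higher), and 4 and 5 in naive dCD (4 higher in each). Of neural loci 4 passed centred and 3 quantile-scaled in each state of dCD, all higher. Of trophoblast loci 1 passed centred in formative dCD, higher, and 1 within 20 kb in the dCD transition difference, lower. Of germ line loci 2 passed centred, 2 quantile-scaled and 1 at 2-fold in formative DKO, all higher. In naive dCD 3 passed under centring, quantile scaling and 20 kb (2 higher in each), and in formative dCD 1 centred and 1 quantile-scaled, higher. Of housekeeping loci 1 passed centred in naive DKO, higher.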

Other observations

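H3K27ac over the regions gained in wild type was also compared between genotypes. In the authors' deposited table, regions gained in wild type had median H3K27ac differences of 1.32 in wild type and 0.46 in DKO, where all regions had 0.33 and 0.05. In formative cells H3K27ac was lower in DKO than in wild type by a median of −0.66 there, and of −0.20 over all regions, in the authors' deposited table. The 2226 genes nearest to gained regions had median RNA differences of 0.73 in wild type and 0.61 in DKO in the authors' deposited table. Over the 21520 regions lower in formative DKO and dCD, H3K27ac stood at −0.69 in formative DKO and RNA of 2300 nearest genes at 0.06, in the authors' deposited table. Tcf15 had RNA differences of −0.46 and 3.59, Utf1 of 1.32 and 3.87 and Klf4 of −0.87 and −2.16 in wild type and DKO, in the authors' deposited table.

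Neighbouring 1 Mb windows of chromosome 13, 65000001–66000000 with 127 regions and 66000001–67000000 with 132, stood apart from the rest of the chromosome. The floxed line differed from wild type there by −1.52 and −1.58 in naive and formative cells in the first window and by −1.58 and −1.52 in the second. DKO differed from wild type by −2.04 and −1.07 and by −2.23 and −1.27. In dCD the values were −0.16 and 0.51 and −0.33 and 0.23, and in formative dCD they were not near the median over all regions of −0.29. These windows were found after the data were seen.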
